A study of Mus musculus with 2 samples.

How the data were processed

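Polyadenylated RNA of mouse adipose tissue was measured in 2 technical libraries of 1 biosample (biological replicate 1), per the labels. RNA was extracted with a kit for lipid-rich tissue and the size range was 350 to 450, per the labels, which give no unit for it. The files were made on the mm10 assembly with the M4 annotation, per the text deposited beside them. The aligner and the quantifier are not given in the sources used here; the column names are those that RSEM writes.

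The authors deposited expected counts per gene and per transcript, which are estimates that need not be whole, per the file headers. The authors also deposited TPM, scaled to the same sum in each library, and FPKM, per the file headers. The share of a gene's TPM taken by each transcript is a percent that the authors deposited. Posterior mean counts and posterior mean TPM stand beside them and were used as alternatives. The gene tables hold 69691 entries, of which 43346 carry mouse gene identifiers, 26248 bare numbers and 97 spike-in names. The last 2 kinds held 0 counts in library 1 and 2 in library 2 and were left out. Symbols, biotypes, coordinates and GC content came from the GENCODE M21 annotation of the same assembly, a later release than the authors' annotation, and 42462 identifiers matched. Identifiers without a symbol held 0.148% and 0.116% of the counts. GC content is that of all annotated transcripts of a gene, and 99.3% of the tested genes had a value.

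Depth was 19954869 and 19256807 expected counts. A transcript of average yield and 1 kb reaches the floor of 3 counts at 0.175 TPM in library 1 and 0.224 TPM in library 2. Reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only.

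Expected counts were rounded to whole numbers for tests. Genes with at least 10 counts summed over both libraries (18261) were tested by a two-sided exact binomial test of the counts of library 2 given the sum, with TMM effective library sizes from edgeR and Benjamini-Hochberg adjustment. Calls needed an adjusted p below 0.05 and a change of at least 2-fold. With 1 library on each side there are no residual degrees of freedom, so this test covers counting error between these 2 libraries, and no replicate check exists. Log2 ratios used 0.5 added to each count. Intervals are 95% exact Clopper-Pearson intervals. The spread beyond counting was the variance of the log ratio less its Poisson part. A gene was taken to share reads where a count was not whole within 0.005.

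The 34 gene lists were fixed before the data were examined, as were the design, the rule for named genes and most alternatives. List levels are medians of TPM over the members, ranked among 10000 random lists of protein-coding genes, and list shifts are medians of log2 ratios ranked among 10000 random lists matched on expression in 20 bins. Ahsp and Muc16 had no match. The rule named the 15 genes with the highest mean TPM, up to 3 members of each list with the highest mean TPM (the highest member of a list with a median under 1 TPM), and the 10 largest and 10 smallest log2 ratios among called genes with at least 100 counts on average. It also named Pparg, Insr, Lpin1, Pkm, Vegfa and the adipocyte identity list for isoforms, and Ucp1, Lep, Xist and Ddx3y in any case. Some genes that the rule names are not reported here. Examples among called genes (Cfd, Cidec, Lipe, Plin1, Eif2s3y, B2m, Pde3b), the set of 76 ribosomal protein genes, the beta-defensin family, and 3 further lists (meiotic germ cell, testis somatic cell, seminal vesicle and prostate) were chosen after the data were seen. So were the 18 lists counted as cell type lists in a test of cell makeup, which were picked when that test was written.

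Alternatives covered other scalings (DESeq2 size factors, total counts), filters, pseudocounts, posterior means, FPKM, other detection limits, an edgeR exact test with a dispersion of 0.01, and each library alone. Removal of the GC trend (40 bins), a restriction to genes under 45% GC, and rescaling without the mitochondrial copies were added after the data were seen. The tests were tested on simulated data for library 2 against library 1 over 18261 genes: without a GC trend, 100% of genes changed 3-fold, 6-fold or 10-fold and 0.011% of unchanged genes were called. With a simulated GC trend, linear at 0.2 log2 per percent, 43.3% of unchanged genes were called, and 0.106% after the trend was removed. With that trend left in, 66% of genes changed 3-fold were called in the right direction. Simulated counts held counting error only, and the trend followed the GC value used for its removal. These rates therefore do not carry over to the data, where 18.3% of tested genes were still called after removal. R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used. Signal tracks were not used here.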

Results

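Polyadenylated RNA was sequenced from adipose tissue, the fat-storing tissue, of a male C57BL/6J mouse aged 10 weeks. The labels describe 1 biosample sequenced as 2 technical libraries, and they hold a single group. Library 2 was performed in 2015 and lies outside the 2014 publication that the labels name. The expected counts assigned to annotated genes summed to 19954869 in library 1 and 19256807 in library 2. Every SD below is therefore the technical spread between n = 2 libraries of 1 biosample, and library and date of preparation cannot be told apart. Intervals cover counting error only. No condition was compared with another.

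Transcripts of fat cells were abundant in both libraries. Car3, a carbonic anhydrase of fat and muscle, stood at 7130 ± 200.03 TPM (SD, n = 2; chromosome 3, annotated gene ENSMUSG00000027559), and Fabp4, a fatty acid carrier of adipocytes, at 5089 ± 1438 TPM. Lpl, the lipase that releases fatty acids from circulating triglyceride, reached 1556 ± 189 TPM. Adipoq, which encodes adiponectin, was at 656 TPM in library 1 and 1486 TPM in library 2. All 12 members of the adipocyte identity list were at 1 TPM or more in both libraries. The median of that list was 110 TPM in library 1 and 555 TPM in library 2. Its median over both libraries, 401 TPM, stood at percentile 100 among 10000 random lists of protein-coding genes.

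Secreted and metabolic genes of fat were measured as well, at levels that ranged widely between genes and libraries. Among adipokines, Cfd (complement factor D, adipsin) was at 69.3 and 4561 TPM in libraries 1 and 2, Retn (resistin) at 216 and 794 TPM, and Lep (leptin) at 77.1 and 165 TPM. The adipokine medians were 42.5 and 178 TPM, with all 12 members detected in both libraries. In lipolysis, Pnpla2, the triglyceride lipase of fat cells, was at 89.6 and 795 TPM, Lipe (hormone-sensitive lipase) at 8.66 and 360 TPM, and the lipid droplet protein gene Plin1 at 2.23 and 349 TPM. The lipolysis medians were 24.3 and 145 TPM. In de novo lipogenesis, the desaturase gene Scd1 was at 2835 ± 50.6 TPM, beside Scd2 at 263 ± 90.6 TPM and Acly at 235 ± 161 TPM. Scd1 and Scd2 share reads and are uncertain. The medians of that list were 57.4 and 116 TPM. In triglyceride synthesis the medians were 18.4 and 78.6 TPM, with Pck1 at 299 ± 250 TPM, Dgat2 at 185 ± 218 TPM and Agpat3 at 103 ± 115 TPM. Insulin signalling genes had medians of 22.6 and 33.0 TPM, with Akt2, which shares reads and is uncertain, at 66.6 ± 52.1 TPM and Pik3r1 at 61.5 ± 15.1 TPM.

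Genes of heat-producing adipocytes were low. Ucp1, the uncoupling protein of brown fat, had 2 counts in library 1 and 4 in library 2, or 0.08 and 0.20 TPM. The thermogenic list had a median of 0.275 TPM in library 1 and 1.85 TPM in library 2, and 3 of its 14 members were at 1 TPM or more in both. Its highest members were Cox8b at 8.24 ± 11.2 TPM, Ebf2 at 6.35 ± 0.438 TPM and Cox7a1 at 4.71 ± 6.66 TPM. Its median over both libraries, 1.45 TPM, stood at percentile 13.1 of random lists. Among depot patterning factors, with medians of 0.705 and 1.56 TPM, Hoxc8 was at 47.3 ± 7.20 TPM, Tcf21 at 12.0 ± 13.8 TPM and Wt1 at 9.29 ± 0.636 TPM.

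Transcripts of the epididymis, the duct in which sperm mature, were more abundant than those of the adipocyte list. All 12 genes of the epididymis list were at 100 TPM or more in both libraries. The list had a median of 2086 TPM in library 1 and 2111 TPM in library 2. Crisp1, a secreted protein that coats sperm, was at 5517 ± 2071 TPM, the lipocalin genes Lcn5 and Lcn8 at 4784 ± 3370 and 3579 ± 2928 TPM, and Adam7 at 3074 ± 917 TPM. Gpx5, an epididymal glutathione peroxidase (ENSMUSG00000004344, chromosome 13, 21286429 to 21292731, mm10), was at 14893 ± 1013 TPM, and Spag11b (ENSMUSG00000059463, chromosome 8, 19140759 to 19143010, mm10) at 9955 ± 134 TPM. Both were among the 15 genes with the highest mean TPM. Genes of sperm-forming cells were present at lower levels. All 12 of the testis germ cell list were at 1 TPM or more in both libraries, with a median of 17.04 and 66.0 TPM. The protamine gene Prm2, which packs sperm DNA, was at 2.94 and 516 TPM, Prm1 at 45 and 257 TPM, and Smcp at 148 ± 17.1 TPM.

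**Figure D1:**
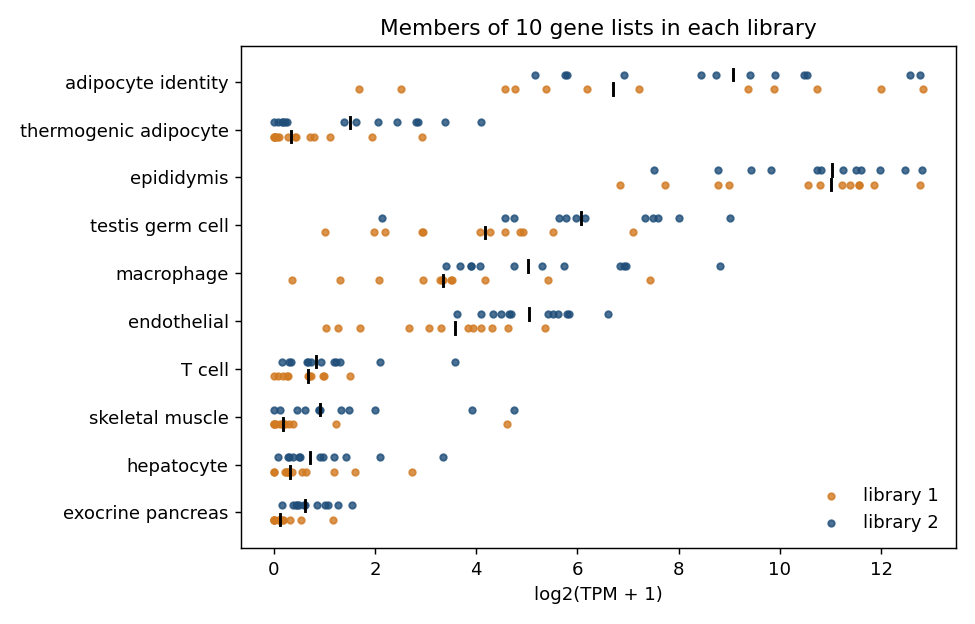
Expression of the members of 10 gene lists, as log2(TPM + 1) on the horizontal axis, with each list on its own line. Points are genes, orange for library 1 and blue for library 2, and the black bars are list medians: the epididymis medians were 2086 and 2111 TPM and the adipocyte identity medians 110 and 555 TPM.

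The further lists of this paragraph, except stromal progenitors, had higher median TPM in library 2. Medians are given here as library 1 and library 2. Mitochondrial genes and their copies took 51.7% of TPM in library 1 and 15.9% in library 2. This lowers the TPM of all other genes more in library 1, so a higher TPM in library 2 need not be a higher scaled ratio. Insulin signalling genes, for example, had medians of 22.6 and 33.0 TPM but a median log2 ratio of -0.73. A median of ratios can also differ from a ratio of medians. Of the 12 insulin signalling members, 4 were called higher in library 2 and 2 lower. The macrophage list had medians of 9.10 and 32.0 TPM, with the lysozyme gene Lyz2, which shares reads and is uncertain, at 311 ± 195 TPM and the complement genes C1qa and C1qb at 70.2 ± 75.1 and 65.3 ± 77.6 TPM. Endothelial genes had medians of 11.2 and 33.2 TPM, with Egfl7 at 54.5 ± 58.2 TPM, Pecam1 at 39.0 ± 21.6 TPM and Cdh5 at 36.0 ± 28.2 TPM. Stromal progenitor genes had medians of 31.2 and 29.9 TPM, led by Ly6a at 150 ± 50.8 TPM, Cd34 at 107 ± 18.9 TPM and Col15a1 at 58.2 ± 24.1 TPM. The extracellular matrix medians were 33.4 and 154 TPM, with Dcn at 917 ± 92.2 TPM, Sparc at 890 ± 476 TPM and Col3a1 at 389 ± 59.1 TPM. Smooth muscle and pericyte genes had medians of 9.46 and 31.6 TPM, with Acta2 at 235 ± 220 TPM, Rgs5 at 95.02 ± 39.2 TPM and Tagln at 88.5 ± 89.7 TPM. Mesothelium genes, a list meant for the lining of the body cavity, had medians of 9.26 and 28.3 TPM. Among them Krt18 was at 127 ± 156 TPM, Krt8 at 94.96 ± 121 TPM, Krt19 at 66.6 ± 86.4 TPM and Upk1b at 36.7 ± 5.49 TPM. Epithelial genes had medians of 1.73 and 24.9 TPM, with Epcam at 110 ± 46.4 TPM, Cldn3 at 90.3 ± 127 TPM and Cdh1 at 43.4 ± 16.1 TPM. Which cells the keratin and epithelial transcripts came from was not tested. Erythroid genes had medians of 0.140 and 12.9 TPM. Their globin genes share reads and are uncertain: Hba-a2 was at 936 ± 900 TPM and Hbb-bs at 769 ± 1005 TPM. The median log2 ratio of stromal progenitor genes was 0.60, with 6 of 12 members called higher in library 2 and 2 lower. With the GC trend removed, that median was -0.14, the extracellular matrix median went from 1.13 to -0.04, the smooth muscle and pericyte median from 1.34 to 0.09 and the mesothelium median from 0.74 to 0.18.

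T cell, B cell, skeletal muscle, hepatocyte and exocrine pancreas genes had medians under 1 TPM in both libraries, again given as library 1 and library 2. T cell genes had medians of 0.605 and 0.785 TPM, with Zap70 at 5.83 ± 7.36 TPM, and B cell genes medians of 0.255 and 0.380 TPM, with Ighm at 102 ± 70.2 TPM. Skeletal muscle genes had medians of 0.135 and 0.875 TPM, with Myl1 at 24.7 ± 1.84 TPM, and hepatocyte genes medians of 0.250 and 0.665 TPM, with Fga at 7.41 ± 2.496 TPM. Exocrine pancreas genes had medians of 0.085 and 0.525 TPM. Schwann cell genes had medians of 1.30 and 4.2 TPM, led by Pmp22 at 86.7 ± 8.10 TPM. Steroidogenic genes had medians of 2.21 and 2.83 TPM, with Cyp17a1 at 21.2 ± 6.45 TPM and Insl3, which overlaps the expressed gene Jak3 and is uncertain, at 22.6 ± 23.6 TPM. The list meant for RNAs without a poly(A) tail had medians of 0 and 1.71 TPM. Its highest member was Hist1h2bc, which shares reads and is uncertain, at 156 ± 45.6 TPM. Whether the Hist1h2bc transcripts carried a tail was not tested. Of the sex linked genes, Xist, transcribed from an inactive X chromosome, was at 0.07 and 0.03 TPM, and the Y-linked gene Ddx3y at 40.5 and 30.9 TPM. The label male was thus matched by these genes, and the list medians were 19.7 and 10.9 TPM.

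The remaining lists describe general cell activity, with medians in the same order. Immediate early genes had medians of 6.84 and 34.7 TPM, with Egr2 at 72.2 ± 54.8 TPM, Zfp36 at 56.8 ± 29.0 TPM and Dusp1 at 41.4 ± 31.8 TPM. Heat shock genes had medians of 62.0 and 100.1 TPM, with Hspa5 at 861 ± 8.66 TPM and Hsp90ab1 at 689 ± 26.3 TPM. Circadian clock genes had medians of 5.06 and 17.05 TPM, with Tef at 32.2 ± 20.5 TPM, Nr1d2 at 26.1 ± 5.90 TPM and Nr1d1 at 16.6 ± 19.5 TPM. Nuclear genes of oxidative phosphorylation had medians of 54.1 and 136 TPM, with Atp5b at 531 ± 405 TPM, Cox4i1 at 446 ± 559 TPM and Atp5a1 at 297 ± 94.2 TPM. Reference genes had medians of 135 and 463 TPM, with Eef1a1, which shares reads and is uncertain, at 5215 ± 2350 TPM and B2m at 3342 ± 1275 TPM. Cytosolic ribosomal protein genes had medians of 167 and 1003 TPM, with Rplp1 at 17.3 and 3472 TPM, Rps27 at 1080 and 1401 TPM and Rps12 at 300 and 1897 TPM. Many of these have processed copies that share reads and are uncertain. Over the mean of both libraries, 28 of the 34 lists had a median of 1 TPM or more.

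Mitochondrially encoded transcripts took a large and unequal part of both libraries. The 13 mitochondrial messenger RNAs had a median of 15971 TPM in library 1 and 3551 TPM in library 2. The mitochondrial chromosome held 19.4% of the counts of library 1 and 4.11% of those of library 2. With the copies on chromosome 1 that share its reads, these shares were 26.0% and 6.20%. The highest mitochondrial genes by TPM were mt-Atp8 at 119713 and 33805 TPM, mt-Co1 at 56214 and 17371 TPM, and mt-Cytb at 32830 and 9323 TPM. The rank of mt-Atp8, a transcript of length 204, holds in TPM and not in counts. It had 77248 and 18951 expected counts, against 1305653 and 316422 for mt-Co1. Mitochondrial genes and their copies on chromosome 1 made up 13 of the 15 genes with the highest mean TPM, and the copies (among them Gm28661, Gm10925 and Gm28437) share reads with the mitochondrial genes and are uncertain. The 10 genes with the highest mean TPM took 43.0% of TPM in library 1 and 14.5% in library 2, or 21.7% and 6.67% of expected counts.

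Detection overlapped, while levels differed widely between the libraries. At 1 TPM or more, 13601 genes were found in library 1, 15967 in library 2 and 13220 in both. Genes found in library 2 alone (2747) had a median transcript GC content of 56.1%, against 43.3% for the 381 found in library 1 alone. Across 16348 genes at 1 TPM or more in either library, log2(TPM + 1) gave a Pearson r of 0.767 and a Spearman rho of 0.730; this is a correlation across genes, which are not independent replicates. A chi-square of the counts was 421 per degree of freedom, so the libraries differed by far more than sampling noise. The spread between the libraries beyond counting error, as a coefficient of variation, was 0.872 over 12085 genes with at least 100 counts on average, and 0.748 over those with 1000 counts or more.

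Many genes differed between the libraries, in both directions. By the exact binomial test with Benjamini-Hochberg adjustment, which compares these 2 libraries and not conditions, 5514 of 18261 genes were at least 2-fold higher in library 2 and 3407 at least 2-fold lower. Plin1 was higher by a log2 ratio of 6.52 (95% exact interval 6.18 to 6.91), Lipe by 4.72 (4.57 to 4.88), Cfd by 5.30 (5.21 to 5.40) and Cidec by 2.66 (2.60 to 2.72). With the trend of the ratio with GC content removed, a step chosen after the data were seen, these ratios were 3.75, 2.29, 1.99 and 0.49, so that Cidec no longer reached 2-fold. Of the adipocyte identity list, 5 of 12 members were higher and 2 lower, the same counts as when adjusted over the list alone, with Lpl at -1.07 and Cd36 at -1.22. With the GC trend removed, 1 member, Plin1, was higher and 1, Cebpa, was lower. Cebpa went from 1.66 to -2.53, while Lpl stood at -0.50 and Cd36 at 0.36. Cebpa has a GC content of 61.2%. Ratios at 60% GC or more had a 25th to 75th percentile of 2.79 to 5.60, so subtracting a median leaves such genes uncertain. The value does not show that Cebpa was lower in library 2. Against a floor of 3 counts per library, Ccdc124 (0 and 508 counts) was at least 129-fold higher, Map1s (0 and 486 counts) at least 124-fold and Sf3b5 (0 and 512 counts) at least 130-fold. The ribosomal protein gene Rpl36, with 0 counts in library 1, was at least 770-fold higher and shares reads. So do Hba-a1, Hist2h2aa2, Rpl27-ps3, Gm20390 and Gm20683, which had 0 counts in library 1 as well, and Rps4l (0 and 507 counts) is a paralog of a ribosomal protein gene. Hba-a1 and Hba-a2 together were higher by 2.49. Scaling to total counts moved every log2 ratio by 0.44 and changed the split to 6816 higher and 1196 lower, so that 85.1% of calls were higher in library 2 in place of 61.8%.

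The 10 genes lowest in library 2 all had fractional counts in a library and are uncertain. They included mt-Co2 with a log2 ratio of -5.72 (-5.77 to -5.66), mt-Atp6 at -3.99, mt-Co3 at -3.71 and Gm28439, a copy on chromosome 1, at -11.70. The others were H3f3c at -4.53, 2210418O10Rik at -4.42, and Gm28037, Gm6829, Gm20547 and ENSMUSG00000103508, each with 0 counts in library 2. All 13 mitochondrial messenger RNAs were at least 2-fold lower in library 2, over all genes tested and adjusted over the list alone. With the GC trend removed, 10 of the 13 were. Among genes with whole counts, Eif2s3y was lower by a log2 ratio of -1.35, B2m by -1.53 and Pde3b by -1.50. With the GC trend removed these were 0.23, -0.19 and -0.16, and none reached 2-fold.

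The log2 ratio between the libraries was graded with the GC content of the transcript. Over 453 genes under 40% GC its median was -1.48, and 93.4% of them were called lower in library 2. Between 50% and 55% GC the median was 0.77, and between 55% and 60% it was 2.54. Over 349 genes at 60% GC or more it was 4.14, with 95.1% called higher. The Spearman rho with GC content was 0.893 across 12045 genes, and that with transcript length -0.277. When the GC trend of the log2 ratio was removed, 1816 genes were higher in library 2 and 1527 lower. Of the 5514 genes first called higher, 1564 remained so and 388 were then called lower. Of the 3407 called lower, 354 remained so and 0 were called higher. The 25th to 75th percentile of ratios was 2.79 to 5.60 at 60% GC or more, against -1.71 to -1.29 under 40%. Removal of a median leaves that spread, so calls after removal are less certain for GC-rich genes.

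**Figure D2:**
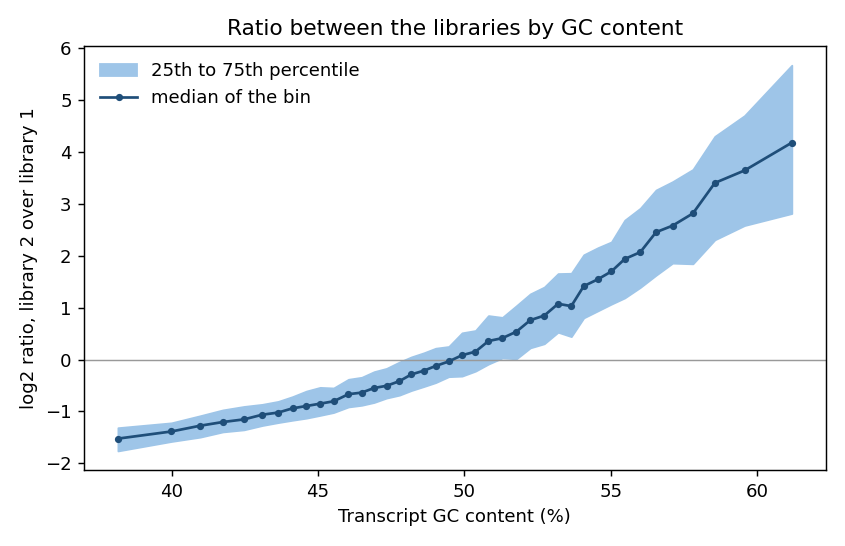
The log2 ratio of library 2 over library 1 (vertical axis) against transcript GC content in percent (horizontal axis), in 40 bins of genes with at least 100 counts on average. The line gives the median of each bin and the band its 25th to 75th percentile: the ratio lay below 0 under 45% GC and above 2 over 57% GC.

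The ribosomal protein genes show the grading within a single complex. Over 76 of them, the 25 with the lowest GC content had a median of 407 TPM in library 1 and 891 TPM in library 2, and the 25 with the highest GC content 55.6 and 1002 TPM. Rpl8 was at 1.82 and 856 TPM and Rps15 at 3.55 and 1407 TPM, while Rps24 was at 3123 and 1909 TPM. These 3 were chosen after their values were seen.

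**Figure D3:**
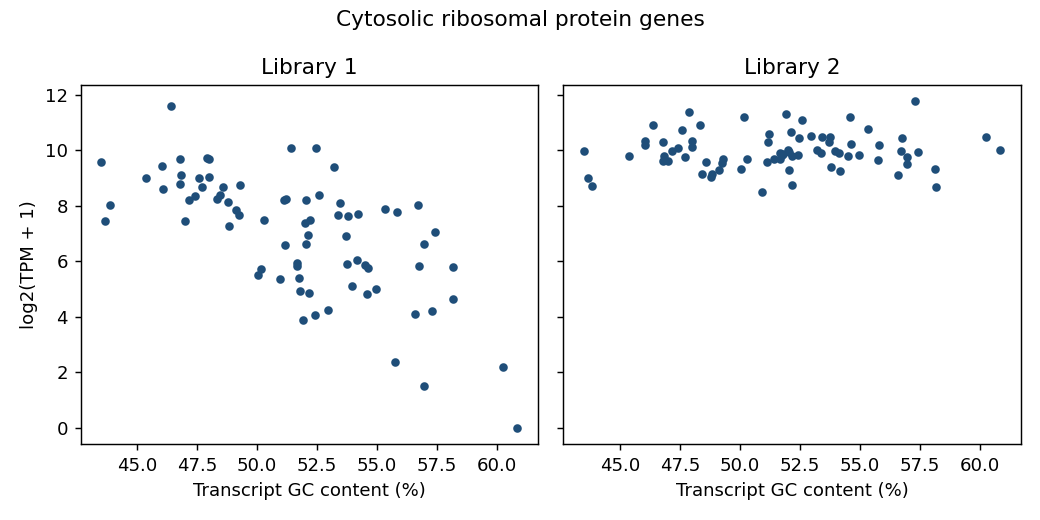
Expression of 76 cytosolic ribosomal protein genes as log2(TPM + 1) (vertical axis) against transcript GC content in percent (horizontal axis), in library 1 (left) and library 2 (right), each point a gene. The 25 genes with the highest GC content had a median of 55.6 TPM in library 1 and 1002 TPM in library 2.

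Of the 34 lists, 9 had a median log2 ratio outside the central 95% of random lists matched on expression, and 7 of these lay above it. Erythroid genes had a median of 4.28 (percentile 100), epithelial genes 2.94 (percentile 99.9), skeletal muscle genes 2.07 (percentile 99.0), cytosolic ribosomal protein genes 1.94 (percentile 99.8), endothelial genes 1.75 (percentile 98.9), macrophage genes 1.74 (percentile 98.9) and nuclear genes of oxidative phosphorylation 1.48 (percentile 98.9). With members at 0 counts held at the floor of 3, the skeletal muscle median was 1.83 and the erythroid and epithelial medians did not change. For erythroid genes this check could not move the median. Over 6 tested members it lay between Hbb-bs (4.18) and Hbb-bt (4.39), which share reads and are uncertain. Without the filter on counts the erythroid median was 1.70. Mitochondrial messenger RNAs had a median of -2.71 (percentile 0) and the sex linked list -1.35 (percentile 0.52). The adipocyte identity median was 0.15 (percentile 60.3) and the epididymis median -0.66 (percentile 6.88), both inside the central 95%. With the GC trend removed, the macrophage (0.38, percentile 94.2), endothelial (0.36, percentile 94.4) and sex linked (0.01, percentile 49.3) lists lay inside it. The testis germ cell (0.71, percentile 99.5), exocrine pancreas (1.31, percentile 99.8) and depot patterning (-0.77, percentile 0.75) lists then lay outside it. The other 6 stayed outside with medians of 2.13 (erythroid), 1.00 (epithelial), 1.17 (skeletal muscle), 1.63 (ribosomal protein), 0.66 (oxidative phosphorylation) and -1.14 (mitochondrial). Only 7 of 12 exocrine pancreas and 9 of 12 skeletal muscle members were tested. The median levels of these 2 lists in library 1, 0.085 and 0.135 TPM, lay under the floor of 0.175 TPM for 1 kb. Scaling to total counts turned the sign of the hepatocyte and depot patterning medians, from -0.09 to 0.35 and from -0.39 to 0.05. The depot patterning median was also slightly above 0, at 0.008, without the filter on counts. With 1 library on each side, these percentiles describe the libraries and carry no p-value. The random lists were not matched on GC content, so a place outside the central 95% after removal can still reflect it.

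Transcript estimates differed between the libraries as well. Of 7275 genes with several annotated transcripts and at least 100 counts in both libraries, 5086 (69.9%) had the same dominant transcript in both. Insr, Lpin1, Vegfa, Adipoq, Fabp4, Lpl, Slc2a4 and Car3 kept theirs. The main Adipoq transcript took 100% and 99.3% of the gene's TPM, and that of Lpl took 99.9% and 90.6%. In Pkm, 2 transcripts with the same coding length stood at 50% each in library 1, and in library 2 the first of them took 84.1%. In Pparg, the regulator of fat cell formation, the transcript with a coding length of 475 codons took 58.7% in library 1, while that of 505 codons took 71.9% in library 2. The Aqp7 transcript of 6 exons took 88.8% in library 1 and that of 8 exons 96.5% in library 2. Plin4, Cidec and Cd36 also changed their dominant transcript, between forms that overlap over most of their length. Plin1, with 65 counts in library 1, fell under the limit of 100 counts. Its highest transcript changed too, from 1 with 58.1% in library 1 to another with 79.3% in library 2. Among 2116 genes whose dominant transcript changed and had a GC value for both forms, the form of library 2 had the higher GC content in 1648 (77.9%).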

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

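Removal of the GC trend, the restriction by GC content and rescaling without the mitochondrial copies were chosen after the data were seen. No paired analysis was possible because the labels hold 1 group. Genes detected in both libraries fell to 8352 at 5 TPM and ranged from 13601 to 15967 in each library alone. The correlation moved from 0.767 to 0.722 with a pseudocount of 0.1, 0.858 over all genes above 0, 0.693 over genes with 100 counts on average, 0.787 with posterior means and 0.954 under 45% GC. Genes higher in library 2 numbered 3673 at 100 counts on average, where fewer genes were tested, and 1816 without the GC trend. Genes lower numbered 1196 with total counts, 6862 with no minimum fold and 1527 without the GC trend. The spread was 0.748 at 1000 counts, 0.751 by the edgeR common dispersion and 0.459 without the GC trend. The epididymis level of 2579 TPM became 2431 with posterior means, 1590 and 1589 as means of logs with pseudocounts 1 and 0.1, 3412 without mitochondrial genes and 4325 without their copies too, and 2086 to 2111 in single libraries. The thermogenic level was 0.275 to 1.85 TPM in single libraries. Dominant transcripts agreed in 1534 genes at 1000 counts, out of 2018. Without the GC trend 10 of 34 lists turned sign. The sex linked list, from -1.35 to 0.011, was the one that started outside the central 95% of random lists, and the other 9, inside it both times, included the thermogenic (1.34 to -0.26), extracellular matrix (1.13 to -0.04), Schwann cell (0.98 to -0.21), epididymis (-0.66 to 0.09) and stromal progenitor (0.60 to -0.14) lists. Lists outside the central 95% numbered 9 under every alternative, but not the same 9: without a filter skeletal muscle (1.23) came inside and RNAs without a poly(A) tail (1.95) outside, and without the GC trend 6 of the first 9 stayed outside. Another scaling moves all ratios alike, so it cannot change a percentile. The mitochondrial list has no value under rescaling and was left out there. Except where a value above shows it, the cause was not tested. Depth limits genes near 3 counts, such as Ucp1.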

Other observations

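The tests of GC bias in either library, of epididymal tissue, of carry-over and of testis tissue or sperm were chosen after the results were seen; those of transcript length, cell makeup and split reads were written before theirs. A further gene family with abundant members was that of the beta-defensins. Of 43 beta-defensin genes, which encode small antimicrobial proteins, 32 were at 1 TPM or more in both libraries and 20 at 100 TPM or more. Defb20 was at 4057 ± 897 TPM and Defb48 at 3668 ± 1833 TPM (SD, n = 2). Spink8 at 2578 ± 1242 TPM, Spink11 at 2427 ± 347 TPM and Cuzd1 at 1677 ± 101 TPM were abundant as well. These genes were chosen after their values were seen. Genes of the seminal vesicle and prostate were near 0, with a list median of 0 TPM, and 2 of 10 members, Svs5 and Pate4, reached 1 TPM in both libraries. Pate4 overlaps the expressed gene Pate2 and is uncertain.

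The log2 ratio between the libraries was graded with GC content. The cytosolic ribosomal protein genes, whose products are made in similar amounts, bear on which library carries the grading: over 76 of them the Spearman rho of TPM with GC content was -0.651 in library 1 and 0.073 in library 2. GC content bias of library 1 is a candidate explanation, and the value in library 2 argues against GC bias of library 2 as the source, though many of these genes share reads with processed copies. Transcript length had a partial rho of -0.247 given GC content, against 0.891 for GC content given length. This argues against length as the main source, but a weaker relation with length remained. Its part in the list shifts was not tested. A different cell makeup of the RNA stays open for what the GC trend leaves. Of 5 cell type lists outside the central 95%, 3 stayed outside after its removal (6 of 9 over all lists). This count cannot decide the question, because the random lists were matched on expression and not on GC content. The 25th to 75th percentile of ratios ran from 1.66 to 3.51 at 55% to 60% GC, against -1.71 to -1.29 under 40%. The erythroid and epithelial lists had median GC contents of 55.7% and 55.4%. The medians of the 3 lists that stayed outside were smaller (erythroid 4.28 to 2.13, epithelial 2.94 to 1.00, skeletal muscle 2.07 to 1.17). With lists that entered, 5 cell type lists lay outside after removal. The erythroid median rests on 6 tested members, among them globin genes that share reads, and was 1.70 without the filter on counts. Hba-a1 and Hba-a2 together were higher by 2.49. No difference between groups was tested as a biological explanation, since the labels give 1 group.

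Epididymal transcripts were abundant in libraries labelled adipose tissue. The 12 of 12 genes of the list at 100 TPM or more in both libraries, with Crisp1 highest in library 1 and Lcn5 in library 2, are the observation itself and do not test epididymal tissue collected with the fat, which stays open. Genes with fractional counts held 0% of the list's counts, which argues against reads split between copies of a gene family. The ratio of the medians of the libraries was 1.012, which argues against carry-over from another sample into 1 library. By other measures the libraries were less equal. The median log2 ratio of the list was -0.66, with 2 of 12 members called higher in library 2 and 4 lower. Without mitochondrial genes and their copies, the list took 5.465% of TPM in library 1 and 3.688% in library 2. The labels name no depot, and carry-over that reached both libraries alike, or entered the RNA before they were made, was not tested.

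Spermatid transcripts were present, and neither source could be excluded. With genes that overlap another expressed gene left out, the lowest median of the meiotic and testis somatic lists was 1.265 TPM, above the 1 TPM set, after the results were seen, for testis tissue collected with the fat. That value is low and fragile: the full meiotic and testis somatic lists stood at percentiles 24.7 and 14.5 of random lists, and leaving out Insl3 alone, which overlaps Jak3, gave 0.800 TPM in library 1. Of the testis somatic cell genes, 5 reached 1 TPM in both libraries without overlapping genes and 6 with them, so sperm inside the collected epididymis alone could not be decided. Of the 12 meiotic genes, 7 reached 1 TPM in both libraries. The most abundant members that overlap no other expressed gene were Cyp17a1 at 21.2 TPM and Mael at 22.1 and 16.0 TPM. Cyp17a1 and Insl3 also belong to the steroidogenic list. Other members were under 1 TPM in both libraries. Among them were the testis somatic genes Fshr (0.03 and 0 TPM), Amh (0 and 0.15 TPM) and Lhcgr (0.25 and 0.25 TPM). The meiotic genes Stra8 (0.06 and 0 TPM) and Dmc1 (0.58 and 0.30 TPM) were as well.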
